A study of Mus musculus with 8 samples.

How the data were processed

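Gene expression was measured in right fronto-parietal cortex of 16 mice on 8 Agilent 2-colour arrays. The 4 groups were floxed control, Il6-deficient control, floxed cryolesioned and Il6-deficient cryolesioned animals, with 4 animals in each. Each array held total RNA of 2 different animals, 1 labelled with Cy5 and 1 with Cy3, and the labels name the 4 animals of a group as biological replicates. The arrays formed a closed loop with 2 arrays of opposite dye on each of its 4 sides. The control side paired the control groups, the lesion side paired the cryolesioned groups, the floxed-lesion side paired floxed cryolesioned with Il6-deficient control animals, and the deficient-lesion side paired Il6-deficient cryolesioned with floxed control animals. No array held cryolesioned and control animals of the same genotype, so each cryolesion effect was estimated through the other genotype. All arrays came from 1 slide and 1 scan, so slide and scan could not be tested as batches.

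Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1 under its 2-colour gene expression protocol, with Cy5 read as red and Cy3 as green. The deposited scanner files give the median intensity of each spot and of its local background in both channels, without normalization. They also give processed intensities which, per the file headers, were background-subtracted and dye-normalized by the scanner software, and a log10 ratio of those red over green values. The log10 ratio, deposited by the authors in the scanner files, served only to establish the scale and direction of the authors' value table. That table holds 1 column of log2 ratios per array, which the authors deposited without stating background correction or normalization. Its columns rose with log2 red over green. Across the probes used for testing, they correlated at 0.966 to 0.977 with the loess-normalized ratios and had slopes of 1.11 to 1.25 on them. The column medians were 0.0030 and -0.0045 for control-side arrays 1 and 2, and 0.0021 and 0.0019 for the floxed-lesion side. They were 0.0050 and 0.0029 for the lesion side, and 0.0043 and -0.0015 for the deficient-lesion side. Direction and centring were thereby settled, while the exact scaling behind the slopes stays unknown.

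The design written in advance assumed mean spot signals. Median signals were used in their place, because the scanner files used here hold no mean signal column. Background was corrected with normexp on the median signals and the background medians, with an offset of 50, and ratios were normalized within each array by loess. Control spots and spots marked as outliers by the scanner software had weight 0 in the loess and were then left out; 115 to 194 spots per array were so marked and 0 were saturated. Spots of the same probe were averaged. Probes were kept if well above background in at least 4 of the 16 channels, whatever the group, which left 37352 probes. Of 56605 probes without controls, 32989 were named by matching their RefSeq accession, without version, to a RefSeq gene table of assembly GRCm38.p6, and 23616 were not named. Where a gene had several probes, the probe with the highest mean log2 intensity was used. This gave 29363 tested features, of which 16848 were named genes and 12515 unnamed probes; all are called genes in the counts. Among 6258 genes with several probes, 1 had probes called in opposite directions for cryolesion in floxed animals.

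Ratios were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 3 group coefficients and an intercept for the dye effect of each gene. The fit had 4 residual degrees of freedom and a prior of 2.95. Changes with a Benjamini-Hochberg adjusted p under 0.05 were called, and changes are log2 differences with standard errors (SE). The contrasts were cryolesion within each genotype, genotype within each state, genotype as the mean of both states, and the interaction. Levels per animal are log2 channel intensities after loess and Aquantile normalization between arrays. Where a gene was not well above background in any animal of a group, a lower bound of the fold was given, and no fold where this held for both groups. It set the brighter group's mean against the dimmer group's mean of, per animal, the higher of its own signal and the lowest signal among probes well above background. Each group held 2 animals labelled with Cy5 and 2 with Cy3.

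Before the data were examined, 33 gene lists were fixed with 735 members, of which 722 had a named probe. Sex-linked genes were described and the other 32 lists were tested with camera at its preset correlation, with camera at an estimated correlation, and with fry, each adjusted over the 32 lists of a contrast. Camera compares a list with the other genes, whereas fry tests whether its genes move, on balance, in a common direction. Counts of members past the threshold are given over all genes and adjusted over the list alone. Some genes stand in several lists, such as Timp1 among the reactive astrocyte, matrix and STAT3 lists.

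The genes named in the text followed a rule fixed at the same time. Per contrast it took the 10 largest rises and the 10 largest falls among called genes with a symbol. Where fewer than 5 passed, it also took the 5 with the smallest p, named as not passing. Il6, Il6ra, Il6st, Socs3, Stat3, Gfap, Mt1, Mt2, Cx3cr1, Tmem119, Aif1 and sex-linked genes were always included, as were up to 4 members of each list with the smallest p. Predicted genes and clone names counted only where no others filled the places.

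The fit was tested on simulated ratios of 29359 genes with the residual spread of the data, with 50 genes changed at each of 4 sizes. For a log2 change of 1 it called 33 of 50 in either cryolesion contrast, 38 of 50 for genotype in controls, 41 of 50 for genotype in cryolesioned animals, 45 of 50 for the mean of both states and 15 of 50 for the interaction. For a change of 2 the interaction called 40 of 50. The number of arrays limits the precision: the median SE was 0.12 for a cryolesion contrast, 0.11 for genotype within a state, 0.06 for the mean of both states and 0.17 for the interaction.

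The alternatives covered background correction, offset, scaling, the dye intercept, the filter, a separate-channel fit, array weights, a trended and robust variance, all probes, the authors' value table, a replicate block and each array left out. After the data were seen, sex as a covariate, a dye intercept for each end of the slide, the removal of genes on the sex chromosomes, and the microglia list without Cx3cr1 were added. Slide as a random block was not run because there was 1 slide.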

Results

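Total RNA from right fronto-parietal cortex was compared between floxed mice and mice deficient in microglia-derived Il6, with or without a cryolesion, a focal injury made by freezing the cortex. The 16 animals fell into 4 groups of 4 and were hybridised in pairs on 8 arrays. Between 59.2% and 65.9% of probes were well above background in each channel. Median spot intensity was 111 to 144 in Cy5 and 45 to 59 in Cy3, and 0 spots were saturated. The design asks what the cryolesion changed in each genotype, what Il6 deficiency changed in each state, and whether the cryolesion response differed between genotypes.

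Il6, which encodes the targeted cytokine, was read by 2 probes and lay near the detection limit in whole cortex. Its brighter probe was well above background in 3 of 4 floxed cryolesioned animals and in 0 of 4 animals of each other group. The mean log2 intensity of Il6 was 5.92 ± 0.06 (SD, n = 4) in floxed controls and 5.90 ± 0.10 in Il6-deficient controls. After cryolesion it was 6.50 ± 0.27 in floxed and 6.13 ± 0.08 in Il6-deficient animals. By the group means of the brighter probe, Il6 in floxed cryolesioned animals was thus at least 1.44-fold the level of floxed controls. It was at least 1.29-fold that of Il6-deficient cryolesioned animals, although floxed cryolesioned animal 3 (6.20) lay within their range (6.01 to 6.21). Between groups that were both not well above background no fold of Il6 was given. An exact permutation test over 70 splits gave p = 0.0286 for cryolesion in floxed animals, the smallest p it allows, and p = 0.0571 for genotype after cryolesion. For cryolesion in Il6-deficient animals the exact permutation p was also 0.0286, on levels that were not well above background in either group. The Il6 probes were well above background in 3 and 1 of the 16 channels. The filter required 4, so Il6 is not among the 29363 tested features. Fitted without the filter, the dimmer probe had a log2 ratio of 0.18 ± 0.10 (SE) for cryolesion in floxed and 0.21 ± 0.10 in Il6-deficient animals. For genotype after cryolesion its ratio was -0.07 ± 0.09, against -0.32 ± 0.15 for the brighter probe. The genotype difference in Il6 after cryolesion therefore rests on the brighter probe alone. In limma, fitted over all probes without the filter, the brighter probe's unadjusted p was 0.0181 for cryolesion in floxed animals and 0.0808 for genotype after cryolesion. The first of these was 0.0586 and 0.0520 without control-side arrays 1 and 2, 0.0570 without lesion-side array 2 and 0.0526 without deficient-lesion-side array 2. The deleted part of the gene is not given in the sources used here, so Il6 checks the genotype labels only as far as its probes lie inside that part and as far as cortical Il6 comes from microglia.

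**Figure D1:**
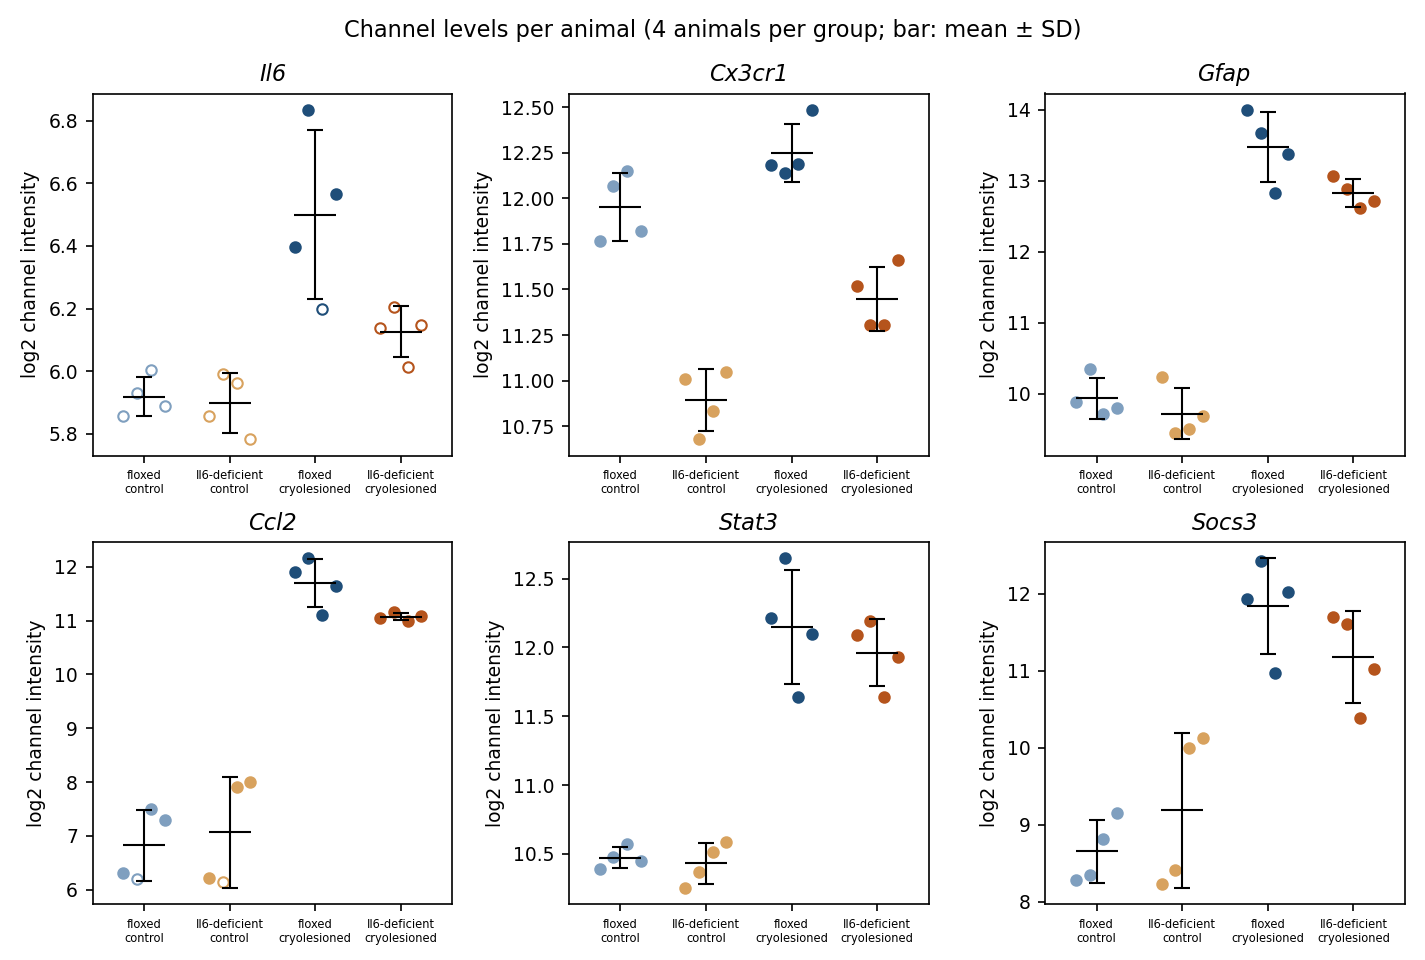
Log2 channel intensity of Il6, Cx3cr1, Gfap, Ccl2, Stat3 and Socs3 (vertical axis) in each animal of the 4 groups (horizontal axis), with filled points well above background, open points not, and bars giving the mean ± SD of 4 animals. Il6 was well above background only in 3 floxed cryolesioned animals, Cx3cr1 lay lower in both Il6-deficient groups (10.89 and 11.45) than in both floxed groups (11.95 and 12.25), and the other 4 genes were higher after cryolesion.

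The animals differed in sex-linked transcripts. Xist, which is transcribed from the inactive X chromosome of females, was well above background in 3 of 4 floxed controls, 1 of 4 Il6-deficient controls and 0 of 8 cryolesioned animals. Y-linked transcripts were well above background in the other animals, including all 4 of each cryolesioned group. Both cryolesion comparisons therefore also set animals of different sex against each other. By group counts the imbalance was larger in floxed mice. In the fit, where each cryolesion effect runs through the other genotype, it was similar. The fitted Xist ratio for cryolesion was -0.81 ± 0.61 (SE) in floxed and -0.76 ± 0.61 in Il6-deficient animals. By group counts, genotype was unbalanced for sex among controls, whereas all 8 cryolesioned animals were alike. Every contrast draws on all arrays, however, so the fit spread this imbalance over both states. For genotype the fitted Xist ratio was -0.35 ± 0.53 (SE) in controls and -0.30 ± 0.53 in cryolesioned animals. For the interaction it was 0.05 ± 0.86, and sex as a covariate left the median interaction of all genes at 0.0064. Genotype after cryolesion, and the mean of both states, thus also carried sex. With sex as a covariate, added after the data were seen, limma called 799 genes for cryolesion in floxed and 560 in Il6-deficient animals; without genes on the sex chromosomes it called 873 and 787.

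Cryolesion in floxed animals raised chemokine and reactive astrocyte genes. Timp1, an inhibitor of matrix metalloproteinases, rose by a log2 change of 4.88 ± 0.26 (SE, 4 animals per group, adjusted p = 0.00155 in limma). Ccl12 (4.42 ± 0.16), Ccl2 (3.96 ± 0.12), Cxcl10 (4.18 ± 0.77) and Ccl4 (3.82 ± 0.37), chemokines that draw monocytes and other leukocytes, rose as well. So did the heme-degrading enzyme Hmox1 (4.17 ± 0.48), the secreted phosphoprotein Spp1 (4.12 ± 0.70), the tubulin Tubb6 (4.09 ± 0.32), the transglutaminase Tgm1 (4.00 ± 0.17) and the transcription factor Cebpd (3.79 ± 0.24). The falls were smaller and were led by the secreted Wnt inhibitor Frzb (-1.87), the kinase Camkk2 (-1.68), the chemokine Cxcl12 (-1.57 ± 0.13), Gkn3 (-1.54) and the perineuronal proteoglycan brevican, Bcan (-1.50). Selplg (-1.49 ± 0.26), Gpr17 (-1.45 ± 0.28), the synaptic exchange factor Kalrn (-1.42), Myoc (-1.38) and the neuronal inositol kinase Itpka (-1.37) completed the 10 largest falls.

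In all, limma called 896 of 29363 genes for cryolesion in floxed animals, 546 higher and 350 lower, and 353 of them changed at least 2-fold, 286 higher and 67 lower. The number rested on single arrays: it was 60 without control-side array 1, 2140 without control-side array 2, 173 and 405 without floxed-lesion-side arrays 1 and 2, 57 without lesion-side array 2 and 168 without deficient-lesion-side array 2. The separate-channel fit called 4733, 2256 higher and 2477 lower. Median centring in place of loess called 358, and processed intensities 403, of which 350 were higher and 53 lower. Timp1, Ccl2, Ccl7, Ccl12, Cebpd, Gfap, Lcn2, Osmr, Ptx3, Tgm1 and Tubb6 passed with each of the 8 arrays left out in turn.

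The IL-6 and STAT3 list rose in floxed animals after cryolesion, with 9 of 23 measured members higher over all genes, 17 adjusted over the list alone, and a median log2 change of 1.29. Camera gave adjusted p = 3.76e-17 at its preset correlation and adjusted p = 0.217 with an estimated correlation. Stat3, the transcription factor activated by the IL-6 receptor complex, rose by 1.38 ± 0.20 (adjusted p = 0.0213). Socs3, its feedback inhibitor, rose by 1.85 ± 0.25 (adjusted p = 0.0180), and Osmr, which encodes the oncostatin M receptor, by 2.69 ± 0.21. Lcn2, an iron-scavenging acute-phase protein, rose by 2.57 ± 0.11. The receptor genes Il6ra (0.38 ± 0.26) and Il6st (0.34 ± 0.17) did not pass. Mean log2 intensity of Socs3 was 8.65 ± 0.41 (SD, n = 4) in floxed controls and 11.84 ± 0.62 after cryolesion, a wider gap than the fitted ratio; the separate-channel fit gave 2.90 for Socs3 and 4.25 for Lcn2. Controls that shared an array with a cryolesioned animal had higher Lcn2 (8.64 against 6.70), Ccl2 (7.67 against 6.21) and Socs3 (9.52 against 8.32) than the 4 other controls. Without control-side array 1, floxed-lesion-side array 1, lesion-side array 2 or deficient-lesion-side array 2, the adjusted p was 0.0989, 0.0779, 0.112 and 0.0886 for Stat3 and 0.0858, 0.0651, 0.0982 and 0.0756 for Socs3. Median centring gave 0.0517 for Stat3 and 0.0592 for Socs3.

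Inflammatory lists rose with it. Among chemokines and their receptors 11 of 25 members rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 9.13e-12, and adjusted p = 0.147 with an estimated correlation), with Ccl7 at 3.34 ± 0.11. Among cytokines and their receptors 7 of 21 rose (12 higher and 1 lower over the list alone; adjusted p = 3.30e-07, and adjusted p = 0.251 with an estimated correlation), including the alarmin Il33 (1.92) and the interleukin-1 receptors Il1r1 (0.98) and Il1r2 (1.64). Of 28 interferon-stimulated genes 12 rose (26 over the list alone; adjusted p = 3.09e-20, and adjusted p = 0.227 with an estimated correlation), with Oas1a at 1.31 ± 0.12 and Irf9 at 1.17. Of 29 activated phagocyte genes 14 rose and 1 fell (19 and 1 over the list alone; adjusted p = 1.89e-15, and adjusted p = 0.147 with an estimated correlation): the lectin Lgals3 rose by 3.56 ± 0.27 and the lipid carrier Apoe fell by 1.17 ± 0.10. Of 19 complement genes 5 rose (11 higher and 1 lower over the list alone; adjusted p = 8.90e-07, and adjusted p = 0.147 with an estimated correlation), with C4b at 2.01 ± 0.18, C5ar1 at 1.77 and C3 at 1.02 ± 0.16. Antigen presentation genes rose in 2 of 20 cases (5 over the list alone; adjusted p = 9.18e-05, and adjusted p = 0.260 with an estimated correlation), among them the immunoproteasome subunit Psmb8 (1.23).

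Markers of blood-borne cells moved less evenly. The neutrophil calgranulins S100a9 (2.79 ± 0.32) and S100a8 (2.60 ± 0.36) rose and were the 2 of 11 neutrophil genes that passed (2 over the list alone; adjusted p = 0.00806, and adjusted p = 0.326 with an estimated correlation). Plac8 (1.41) was the 1 of 19 monocyte and border macrophage genes that rose, with 10 over the list alone (adjusted p = 2.26e-07, and adjusted p = 0.251 with an estimated correlation). In the lymphocyte list 0 of 16 genes passed over all genes or over the list alone by limma, and camera gave adjusted p = 0.246 (adjusted p = 0.0337 by fry). Erythroid genes had 0 of 9 passing (median 0.29, adjusted p = 0.128). Members of the homeostatic microglia list, as fixed in advance, did not move together. Fcrls (1.28) and Gpr84 (2.13) rose, Selplg fell and 17 of 20 did not pass (2 higher and 5 lower over the list alone, median -0.16, camera adjusted p = 0.484, fry's direction up). Cx3cr1 (0.28), Tmem119 (-0.62) and Aif1 (0.49) were among the markers that did not pass. In the separate-channel fit Cx3cr1 (0.29, adjusted p = 0.0126) and Tmem119 (-0.67, adjusted p = 0.00167) passed, and Aif1 passed without control-side array 2 (0.80, adjusted p = 0.0220).

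Astrocyte genes separated by state. Of 27 reactive astrocyte genes 20 rose and 0 fell (24 over the list alone), with a median log2 change of 1.91 (adjusted p = 1.26e-29, and adjusted p = 0.147 with an estimated correlation). Gfap, the astrocyte intermediate filament, rose by 3.50 ± 0.26 (adjusted p = 0.00353), from a log2 intensity of 9.94 ± 0.29 (SD, n = 4) to 13.47 ± 0.49. Ptx3 was not well above background in any floxed control and was at least 12.8-fold higher after cryolesion (adjusted p = 0.00196). Of 20 homeostatic astrocyte genes 2 fell, the glycolytic enzyme Aldoc (-1.06 ± 0.10) and glutamine synthetase, Glul (-1.04 ± 0.14), with 15 lower and 1 higher over the list alone (median -0.52, adjusted p = 7.87e-08, and adjusted p = 0.227 with an estimated correlation).

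Neuronal genes lay lower. Of 24 excitatory and pan-neuronal genes 3 fell (7 over the list alone, median -0.58, adjusted p = 1.83e-07, and adjusted p = 0.325 with an estimated correlation): the kinase Camk2a (-0.96 ± 0.15), the dendritic microtubule protein Map2 (-0.59) and the cortical transcription factor Tbr1 (-0.89). Of 21 inhibitory neuron genes only the potassium channel Kcnc1 fell (-0.74; 4 over the list alone, median -0.28, adjusted p = 0.00187, and adjusted p = 0.326 with an estimated correlation). Activity-regulated genes went the other way, with Arc (1.75 ± 0.20), Ccn1 (1.94) and Fos (2.00) higher among 24 (10 higher and 3 lower over the list alone, adjusted p = 3.46e-05, and adjusted p = 0.320 with an estimated correlation). Arc lost its call in the separate-channel fit (1.12, adjusted p = 0.178), without control-side array 1 (1.72, adjusted p = 0.0695) and without lesion-side array 2 (1.86, adjusted p = 0.0619). Oligodendrocyte precursor genes Gpr17 and Cspg5 (-1.01) were the 2 of 14 that fell (3 over the list alone, adjusted p = 0.0426, and adjusted p = 0.326 with an estimated correlation), and 0 of 19 myelin genes passed by limma (1 higher and 1 lower over the list alone, median -0.30, adjusted p = 0.124). With sex as a covariate the myelin median was -0.62 (adjusted p = 0.00471), the inhibitory neuron median was -0.15 (adjusted p = 0.0336) and the precursor list did not pass (adjusted p = 0.0621).

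Vascular, matrix and stress genes were mixed. Of 21 vascular activation genes 6 rose and Cd34 fell by 1.13 (11 higher and 1 lower over the list alone, adjusted p = 1.24e-06, and adjusted p = 0.251 with an estimated correlation), with the cholesterol hydroxylase Ch25h at 3.32. Of 24 endothelial and mural genes the contractile protein Tagln rose (2.44) while the transporter Abcb1a (-0.85) and Vtn (-0.65) fell (2 higher and 6 lower over the list alone, adjusted p = 0.367). Of 30 matrix and fibroblast genes 4 rose (10 higher and 1 lower over the list alone, adjusted p = 2.22e-06, and adjusted p = 0.326 with an estimated correlation). Tgfbi rose by 2.66, and Mmp3, not well above background in any floxed control, was at least 5.29-fold higher. Of 28 metallothionein and oxidative stress genes 5 rose (10 over the list alone, adjusted p = 2.28e-05, and adjusted p = 0.227 with an estimated correlation), while the metallothioneins Mt1 (0.97 ± 0.35) and Mt2 (1.86 ± 0.43) did not pass. Mt2 passed with an offset of 16 (adjusted p = 0.0417), median centring (0.0366), the authors' value table (0.0377), the separate-channel fit (0.000372), sex as a covariate (0.0478) and without lesion-side array 1 (0.00386). Mt1 passed in the separate-channel fit (0.00888) and without lesion-side array 1 (0.0102). The cell death list rose in 7 of 26 members (16 higher and 1 lower over the list alone, adjusted p = 9.01e-10, and adjusted p = 0.147 with an estimated correlation), with the inflammatory caspase Casp4 at 1.24 and the death receptor Fas at 1.40. The cell division list rose in 4 of 24 (12 over the list alone, adjusted p = 4.71e-11, and adjusted p = 0.251 with an estimated correlation), led by the replication helicase genes Mcm5 (0.83) and Mcm6 (1.43).

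In each of the lipid, heat shock, ribosomal, metabolic and dissection lists at most 2 members passed over all genes in floxed animals. Of 24 sterol and lipid genes 2 rose, Ch25h and the lipid droplet protein Plin2 (1.76), with 4 over the list alone (adjusted p = 0.000958, and adjusted p = 0.251 with an estimated correlation). Hspb8 (1.07) was the 1 of 14 heat shock genes that rose (4 over the list alone, median 0.48, adjusted p = 0.000136, and adjusted p = 0.267 with an estimated correlation). Rpl18 and Rplp0 were the 2 of 30 ribosomal genes that rose (2 over the list alone, median 0.14, adjusted p = 0.000247, and adjusted p = 0.147 with an estimated correlation). Among 24 oxidative phosphorylation genes 0 passed by limma over all genes or over the list alone, with a median of -0.21 (adjusted p = 0.000407, and adjusted p = 0.326 with an estimated correlation) that was -0.14 with sex as a covariate (adjusted p = 0.0132). Adm (1.65) alone rose among 22 hypoxia and glycolysis genes (2 higher and 1 lower over the list alone, adjusted p = 0.661), whose median of -0.04 and whose camera direction, up, differed in sign. The choroid plexus and meninges list (0 of 17, median -0.38, adjusted p = 0.0800) and the striatum and white matter list (0 of 17, median 0.02, adjusted p = 0.894), which read the dissection, had 0 genes passing by limma over all genes or over the list alone. Over the 32 lists camera called 24 at its preset correlation and 0 with an estimated correlation, and fry called 15.

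Cryolesion in Il6-deficient animals raised many of the leading genes of floxed animals. Cxcl10 rose by 4.85 ± 0.77 (SE, 4 animals per group), Ccl12 by 4.58 ± 0.16, Timp1 by 4.36 ± 0.26, Tubb6 by 4.18 and Tgm1 by 3.80 ± 0.17. Ccl2 (3.76 ± 0.12), Ccl4 (3.65 ± 0.37), Gfap (3.65 ± 0.26, adjusted p = 0.00344 in limma), Ptx3 (at least 10.98-fold) and Hmox1 (3.45) followed. The largest falls were in the claudin Cldn22 (-1.86), Frzb (-1.85), Ddit4l (-1.74), Cadps2 (-1.66), Camkk2 (-1.66), Gpr17 (-1.63), Itpka (-1.61), the vascular sialomucin Cd34 (-1.58 ± 0.14), Kalrn (-1.54 ± 0.23) and the nuclear envelope gene Syne1 (-1.52 ± 0.16). Stat3 (1.77 ± 0.20, adjusted p = 0.0113) and Socs3 (2.00 ± 0.25, adjusted p = 0.0159) also rose in Il6-deficient animals. In the separate-channel fit Socs3 rose by 1.99 in Il6-deficient and 2.90 in floxed animals, so the order of the genotypes depended on the fit. Lcn2 rose by 3.30 and 4.25 in that fit. No gene passed the interaction in either fit.

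In Il6-deficient animals limma called 803 genes for cryolesion, 490 higher and 313 lower, and 356 changed at least 2-fold, 289 higher and 67 lower. The number was 115 without control-side array 1, 173 and 250 without floxed-lesion-side arrays 1 and 2, 253 and 37 without lesion-side arrays 1 and 2, and 127 without deficient-lesion-side array 2. The separate-channel fit called 3016 and array weights 2194, while the log-ratio fit with a replicate block, described below, called far fewer. Median centring called 358, with 181 higher and 177 lower, and processed intensities 326, with 265 higher and 61 lower. The adjusted p of Stat3 was 0.0576, 0.0535, 0.0636 and 0.0629, and that of Socs3 0.0760, 0.0576, 0.0569 and 0.0727, without control-side array 1, floxed-lesion-side array 1, lesion-side array 2 and deficient-lesion-side array 2. Median centring gave an adjusted p of 0.0642 and processed intensities 0.0511 for Socs3.

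Reactive astrocyte genes rose in 18 of 27 cases in Il6-deficient animals (24 over the list alone, median 2.22, adjusted p = 5.26e-27, and adjusted p = 0.158 with an estimated correlation). Interferon-stimulated genes rose in 17 of 28 (26 over the list alone, median 1.11, adjusted p = 2.68e-24, and adjusted p = 0.196 with an estimated correlation), including Ifi27l2a (1.14) and Oas1a (1.36). The IL-6 and STAT3 list rose in 10 of 23 (16 over the list alone, median 0.97, adjusted p = 1.19e-15, and adjusted p = 0.196 with an estimated correlation), with Lcn2 at 2.39 and Cebpd at 3.29. Activated phagocyte genes rose in 12 of 29 and fell in 1 (21 and 1 over the list alone, adjusted p = 5.18e-17, and adjusted p = 0.158 with an estimated correlation). Chemokine genes rose in 11 of 25 and fell in 1 (12 and 1 over the list alone, adjusted p = 1.15e-11, and adjusted p = 0.158 with an estimated correlation). Complement genes rose in 5 of 19 and fell in 1 (7 and 1 over the list alone, adjusted p = 1.20e-05, and adjusted p = 0.158 with an estimated correlation), with C1qa at 0.96 and C1qb at 1.12. Homeostatic astrocyte genes fell in 2 of 20 (4 lower and 2 higher over the list alone, median -0.26, adjusted p = 0.00436, and adjusted p = 0.397 with an estimated correlation). Tbr1 (-1.07) was the 1 of 24 excitatory neuron genes that fell (2 over the list alone, median -0.38, adjusted p = 0.000617, and adjusted p = 0.507 with an estimated correlation). Among activity-regulated genes Ccn1 rose (2.12) and Egr1 fell by 1.33 ± 0.25 (6 higher and 7 lower over the list alone, adjusted p = 0.570). S100a9 (2.17) and S100a8 (1.89) rose among neutrophil genes, and Mt1 (0.90), Mt2 (1.88), Il6ra (0.34), Il6st (0.48), Cx3cr1 (0.43), Tmem119 (-0.52) and Aif1 (0.73) did not pass. Mt2 passed with an offset of 16 (adjusted p = 0.0452), array weights (0.0223), the authors' value table (0.0409), the separate-channel fit (0.00156) and without lesion-side array 1 (0.0361). Cx3cr1 (0.53, adjusted p = 0.000421), Tmem119 (-0.47, adjusted p = 0.0201) and Aif1 (0.98, adjusted p = 0.00325) passed in the separate-channel fit. Camera called 23 of the 32 lists at its preset correlation and 0 with an estimated correlation, and fry called 12.

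In Il6-deficient animals 0 genes passed over all genes by limma in the inhibitory neuron, myelin and oxidative phosphorylation lists. Inhibitory neuron genes had a median of -0.38 after cryolesion (5 of 21 lower over the list alone, adjusted p = 5.27e-05, and adjusted p = 0.308 with an estimated correlation). Myelin genes had a median of -0.53 (3 of 19 lower over the list alone, adjusted p = 0.00839, and adjusted p = 0.557 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.33 (3 of 24 lower over the list alone, adjusted p = 1.37e-07, and adjusted p = 0.254 with an estimated correlation). With sex as a covariate the median was -0.14 for excitatory neuron genes (adjusted p = 0.0343), -0.24 for inhibitory neuron genes, -0.21 for oxidative phosphorylation, -0.86 for myelin and -0.39 for homeostatic astrocytes. Neutrophil genes then had a median of 0.38 against 0.15, matrix genes 0.81 against 0.53, and the heat shock list passed (0.33 against 0.10, adjusted p = 0.0171 against 0.272).

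The cryolesion responses of the genotypes overlapped. Of 1201 genes called in either genotype, 498 were called in both, 356 higher and 142 lower, and 498 of 498 moved in the same direction. Independent lists of these sizes would share 9.11 and 3.73. The contrasts are not independent, because they share the arrays, the residual spread of each gene and the sex imbalance. These numbers are therefore no expected overlap without a common response. Across all 29363 genes the changes correlated at r = 0.794 with a slope of 0.785; genes are not independent replicates. The covariance was 0.0997 against -0.000112 in 20 simulations without effects on the same arrays, where r was -0.00325. The simulations drew noise independently for each gene and held no sex difference. The change was larger in floxed animals for 659 of the 1201 genes, which were selected by their calls, so this number does not test a difference in size. The interaction, which tests whether a cryolesion change differed between genotypes, called 0 genes with limma, 972 at an unadjusted p under 0.05, 0 with the separate-channel fit and 1 without control-side array 2. The genes with the smallest p, which did not pass, were Dlgap3 (0.89), Trank1 (0.98), Igfbp2 (1.11 ± 0.18), Zic1 (-1.26) and Grik5 (0.79). The loop estimates this contrast with the least precision, and a log2 change of 1 was recovered for 15 of 50 simulated genes.

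**Figure D2:**
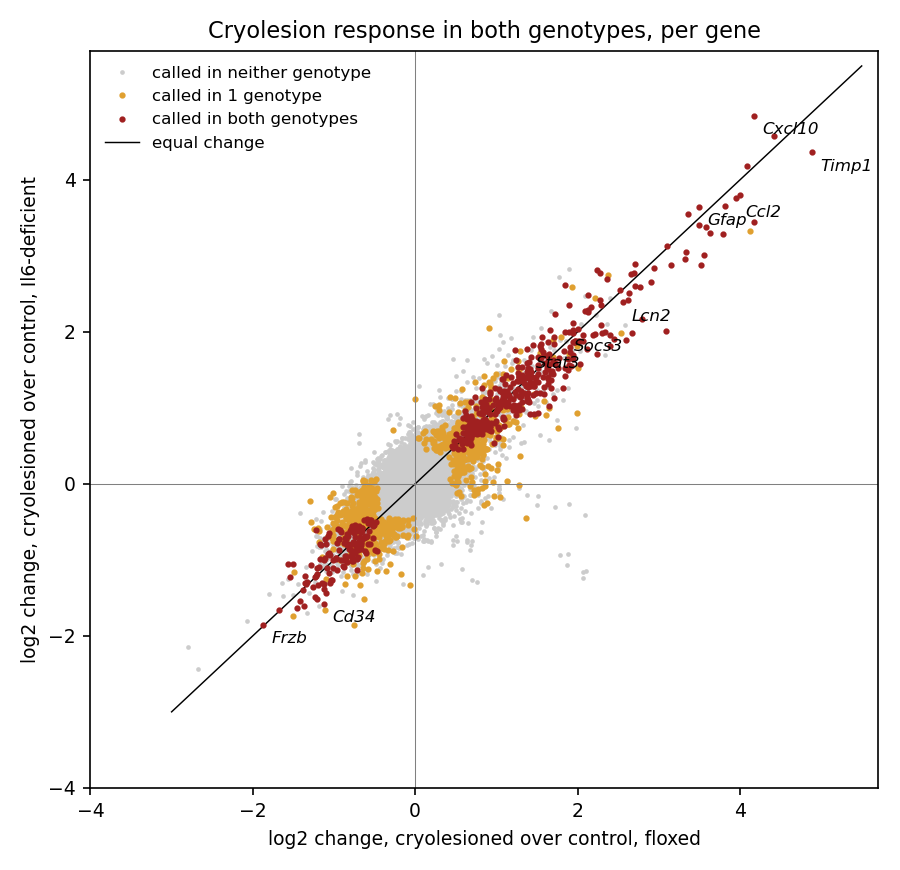
Log2 change with cryolesion in floxed animals (horizontal axis) against that in Il6-deficient animals (vertical axis), with 1 point per gene, grey for genes called in neither genotype, orange for genes called in 1 genotype, red for genes called in both, and a line of equal change. The 498 genes called in both lie near the line, in the upper right (356) and lower left (142).

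For Il6 deficiency averaged over both states limma called 1 gene, with 4145 of 29363 (14.1%) at an unadjusted p under 0.05. Cx3cr1, which encodes the fractalkine receptor of microglia, was lower in Il6-deficient animals by a log2 change of -0.93 ± 0.06 (SE) averaged over both states, a 1.90-fold reduction (adjusted p = 0.0230 in limma), and was the gene called. Its mean log2 intensity was 11.95 ± 0.19 (SD, n = 4) in floxed and 10.89 ± 0.17 in Il6-deficient controls, and 12.25 ± 0.16 and 11.45 ± 0.17 after cryolesion. The other Cx3cr1 probe gave -0.85 ± 0.05 (SE). The next genes by p did not pass: the interferon-induced Ifi27l2a (-0.78 ± 0.06, adjusted p = 0.0672), the mitochondrial translocator protein Tspo (-0.53, adjusted p = 0.0984), Itpka (0.60), C1qb (-0.46) and Casp4 (-0.37). Gfap had a log2 change of -0.43 ± 0.13 (adjusted p = 0.297), Stat3 -0.11 and Socs3 -0.06. Cx3cr1 also passed in the separate-channel fit (adjusted p = 2.13e-07), with array weights, with a trended and robust variance, with an offset of 16, without background correction, under either other filter, over all probes and in the authors' value table. It did not pass in other settings, where its change was -1.002 (adjusted p = 0.131) from processed intensities, -0.93 (0.0814) with scaled ratios, -0.91 (0.0773) with median centring and -0.93 (0.252) without a dye intercept. Its adjusted p was 0.389 without control-side array 1, 0.0548 and 0.221 without floxed-lesion-side arrays 1 and 2, 0.0935 and 0.270 without lesion-side arrays 1 and 2, and 0.144 without deficient-lesion-side array 2. The number of genes called was 0 in each of these, 4 without control-side array 2 and 168 without deficient-lesion-side array 1. With sex as a covariate, which removed the same degree of freedom as a term for control-side array 2, it was 1584.

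Within each state limma called 0 genes for Il6 deficiency. In controls 1299 genes had an unadjusted p under 0.05 and the smallest p belonged to Cx3cr1 (-1.003 ± 0.097, adjusted p = 0.535), Ifi27l2a (-0.99 ± 0.11), Vxn (0.48), Itpka (0.72) and C1qb (-0.59). In cryolesioned animals 2529 did, led by Rasl10a (0.83 ± 0.09, adjusted p = 0.563), Cx3cr1 (-0.85 ± 0.10), Dlgap3 (0.61), Tspo (-0.59) and Kcnh3 (0.69). The separate-channel fit called 1 gene in each state, Cx3cr1, at -1.05 (adjusted p = 9.66e-06) in controls and -0.81 (adjusted p = 0.000272) in cryolesioned animals. Without control-side array 2 limma called 3 genes in controls. Xist was well above background in 3 of 4 floxed and 1 of 4 Il6-deficient controls; with sex as a covariate limma called 0 genes in controls, with 3496 at an unadjusted p under 0.05, and 0 for the interaction, with 1329.

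Gene lists shifted slightly with Il6 deficiency, averaged over both states. Activated phagocyte genes had a median log2 change of -0.29, with 0 of 29 members passing over all genes in limma and 16 lower and 1 higher adjusted over the list alone (adjusted p = 4.95e-14, adjusted p = 0.296 with an estimated correlation, and adjusted p = 0.0664 by fry). Complement genes had a median of -0.21, with 9 lower and 2 higher over the list alone (adjusted p = 8.15e-06, adjusted p = 0.296 with an estimated correlation, and adjusted p = 0.0262 by fry). Interferon-stimulated genes had a median of -0.23 (3 lower over the list alone, adjusted p = 3.65e-12, and adjusted p = 0.351 with an estimated correlation). Reactive astrocyte genes had a median of -0.25 (5 lower over the list alone, adjusted p = 2.28e-10, and adjusted p = 0.310 with an estimated correlation). The IL-6 and STAT3 list had a median of -0.17 (1 lower over the list alone, adjusted p = 2.19e-06, and adjusted p = 0.354 with an estimated correlation). Excitatory and pan-neuronal genes had a median of 0.30 (4 higher over the list alone, adjusted p = 2.58e-08, and adjusted p = 0.351 with an estimated correlation), and oxidative phosphorylation genes 0.13 (adjusted p = 3.44e-06, and adjusted p = 0.351 with an estimated correlation). Homeostatic microglia genes had a median of -0.09, with Cx3cr1 lower over all genes and 3 lower over the list alone (adjusted p = 0.000766, and adjusted p = 0.310 with an estimated correlation); without Cx3cr1 the median was -0.08 (adjusted p = 0.00722, and adjusted p = 0.351 with an estimated correlation). In controls that median was -0.20 (adjusted p = 5.23e-06, adjusted p = 0.268 with an estimated correlation, and adjusted p = 0.354 by fry), and in cryolesioned animals 0.01 (adjusted p = 0.921). Lists that read the dissection moved too: striatum and white matter genes had a median of -0.29 for the mean (15 of 17 negative, adjusted p = 0.0170, and adjusted p = 0.635 with an estimated correlation) and -0.55 in cryolesioned animals (adjusted p = 0.0206, and adjusted p = 0.634 with an estimated correlation). Choroid plexus and meninges genes had a median of -0.13 for the mean (adjusted p = 0.00343, and adjusted p = 0.394 with an estimated correlation). With sex as a covariate the mean of both states gave choroid plexus and meninges genes a median of -0.0010 (adjusted p = 0.277) and striatum and white matter genes -0.47 (adjusted p = 0.00794). Activity-regulated, neutrophil and heat shock genes lost their call with it (adjusted p = 0.243, 0.154 and 0.8289), and myelin (-0.18, adjusted p = 0.00981) and hypoxia genes (0.21, adjusted p = 0.0123) gained one. Camera called 25 of 32 lists for the mean, 21 in controls and 23 in cryolesioned animals at its preset correlation and 0 in each with an estimated correlation; fry called 3, 0 and 1. Besides complement, the fry calls for the mean were ribosomal proteins (median -0.03, adjusted p = 0.0262) and lymphocyte genes (median -0.06, adjusted p = 0.0218).

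**Figure D3:**
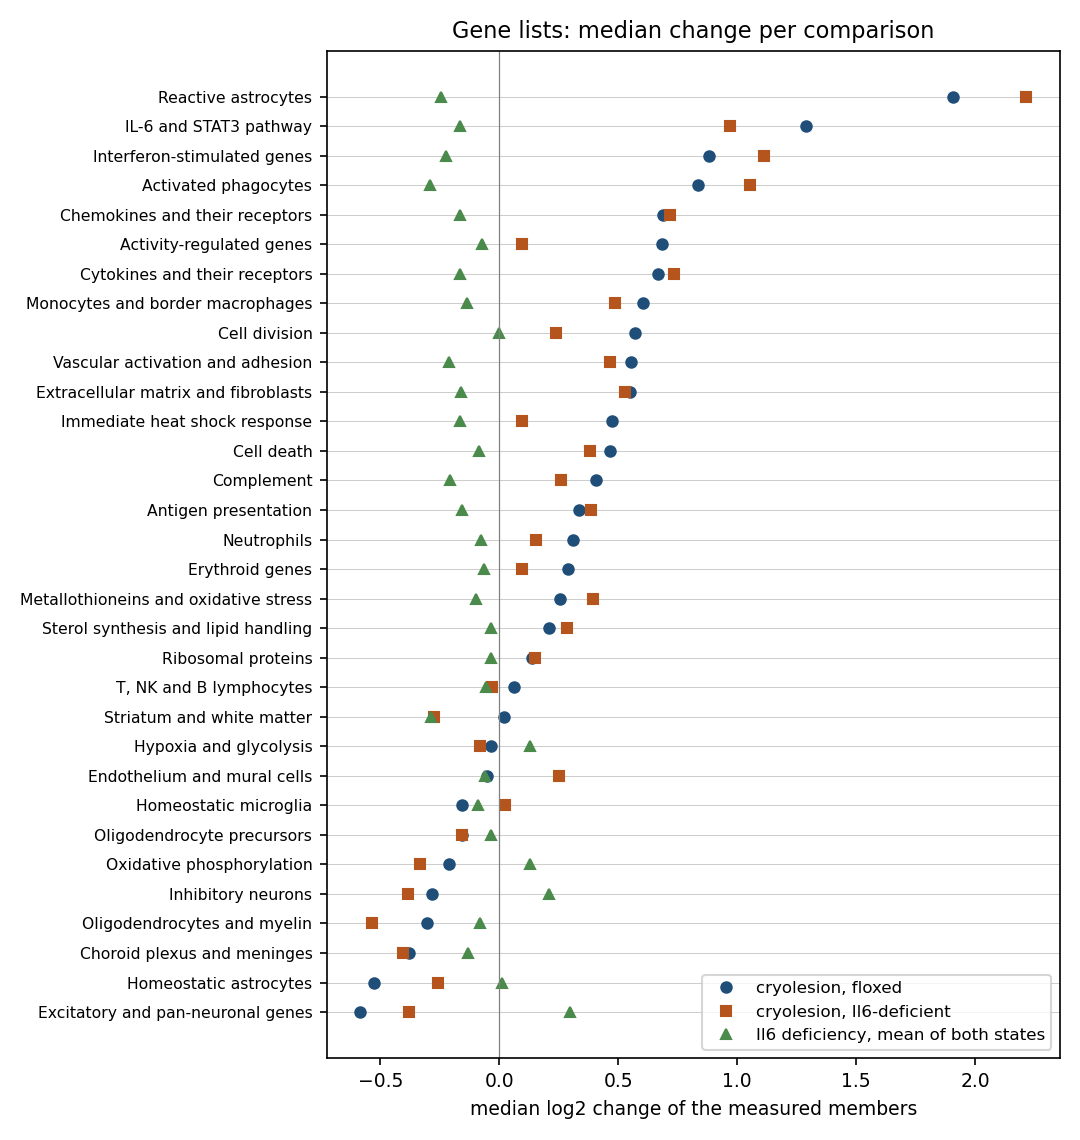
Median log2 change of the measured members (horizontal axis) of the 32 tested gene lists (vertical axis) for cryolesion in floxed animals (circles), cryolesion in Il6-deficient animals (squares) and Il6 deficiency as the mean of both states (triangles). Reactive astrocyte genes had the highest cryolesion medians, 1.91 and 2.22, and every median for Il6 deficiency lay between -0.29 and 0.30.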

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

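The tests of carry-over between channels and of the sex term were chosen after the result was seen; the tests on other splits of the animals were planned.

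Among the 44 group levels of the always-named genes, 2 held an animal far from the other 3, about the share that chance gives at 1 in 20. Cx3cr1 was 12.48 in floxed cryolesioned animal 4, above the nearest value of 12.19. Tmem119 was 8.71 in Il6-deficient cryolesioned animal 2, below the nearest value of 9.11.

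The cryolesion effect of 9 gene lists differed between genotypes by camera at its preset correlation. The median interaction was 0.25 for homeostatic microglia (adjusted p = 0.00184), 0.21 for interferon-stimulated genes (0.0235), 0.28 for homeostatic astrocytes (0.000232), 0.20 for excitatory and pan-neuronal genes (0.0236) and 0.35 for endothelium and mural cells (1.43e-05). It was -0.37 for activity-regulated genes (4.96e-05), -0.24 for cell division (0.000166), -0.10 for oxidative phosphorylation (0.0400) and -0.36 for the heat shock response (0.00614). With an estimated correlation the adjusted p was 0.895 in each, and by fry it was 0.948 in each except endothelium, at 0.874. Members with large values were Cldn5 (0.99) and Slc17a7 (0.80) among the positive lists, and Nr4a1 (-1.96), Egr1 (-1.27) and Arc (-1.02) among activity-regulated genes; 0 genes passed alone in limma, 972 had an unadjusted p under 0.05 and the separate-channel fit called 0.

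Control animals that shared an array with a cryolesioned animal had higher levels of some genes called for cryolesion than controls on the control side. Of 356 genes raised in both genotypes, 27 (7.58%) had all 4 such controls above all 4 others, where chance gives 1.43%; over all genes it was 1.23%. Of 142 genes lowered in both genotypes 9 (6.34%) had them above and 0 below. These calls come from the same arrays, where a higher control enlarges the fitted fall. The selection itself thus favours this excess. Ccl2, Lcn2, Socs3, Isg15 (9.90 against 9.18) and 9 of 28 interferon-stimulated genes showed it, whereas Gfap (9.68 against 9.98), Osmr (7.49 against 7.42) and Ptx3 did not. Whether signal was carried over from the brighter channel is not settled by these values. Of the 45 genes raised more than 4-fold in each genotype 6 (13.3%) were so separated, but a small added signal could miss so strict a criterion. The median difference between the controls that shared an array and the others was 0.18 for these 45 genes. It was 0.06 for the 356 raised genes, 0.14 for the 142 lowered genes and 0.003 over all genes. For single genes carry-over stays open too. Y-linked signal in 2 Xist-positive controls beside Y-positive partners differed from the control-side level by 6.32% and -0.887% of the partner's, and by 0.197% when pooled. For Ccl2 the values were 16.01%, 1.29% and 5.48%. These shares set raw signals of different dyes against each other, and raw Cy5 signals were the higher. The control with the larger shares was labelled with Cy5 and its Y-linked reference controls with Cy3. The shares therefore do not measure carry-over. The labels give no group that would test a biological explanation.

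Sex as a covariate raised the number of genes called for Il6 deficiency, mean of both states, from 1 to 1584. Once groups and dye are fitted, the sex term equals a term for 1 array, control-side array 2, and leaves 3 residual degrees of freedom. That array held the 1 Xist-positive Il6-deficient control beside the 1 Xist-negative floxed control. Sex and whatever else set that array apart cannot be told apart here. Without that array limma called 4 genes.

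The cryolesion counts exceeded all other splits that could be fitted. For floxed animals 1 of 33 splits, the real one, gave as many as 896 genes, and the highest other gave 122; for Il6-deficient animals it was 1 of 33, with 803 against 0. The smallest share such a test can give is 1 of 33. The other splits also mix cryolesioned with control animals, which widens their residual spread. Chance is thus unlikely for both counts but not excluded. For the mean of both states chance was not shown to be unlikely. Of 100 splits 5 gave at least the real 1 gene, with a highest other of 3. At an unadjusted p under 0.05, 5 of 100 gave at least its 4145 genes, with a highest other of 6143. A real count of 0 is reached by every split, so these numbers say nothing about chance for Il6 deficiency in controls (34 of 34, highest other 665), in cryolesioned animals (34 of 34, highest other 667) and for the interaction (100 of 100, highest other 104). Any gene was called by 2 other splits in controls (665 and 4) and 2 in cryolesioned animals (667 and 210). The split with 4 genes parted Xist-positive from Xist-negative controls. What set the splits calling 665 and 667 genes apart was not tested, and each number rests on a single split. Relabelling animals also changes which groups share arrays and their dye balance.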

How the results depend on the processing

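Sex as a covariate, a dye intercept per slide end and the removal of sex chromosomes were chosen after the data were seen. None of the 164 calls of named genes reversed in a setting that tested them, which was 156 of them under the 12-of-16 filter and 160 without sex chromosomes. Array weights kept all 164. Calls lost numbered 57 from processed intensities, 53 with median centring, 25 without a dye intercept and 3 in the separate-channel fit, and between 15 and 124 with 1 array left out. The cause of these losses was not tested, apart from the lost degree of freedom when an array is left out. The median of all genes stayed within 0.06 of 0.

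For cryolesion in floxed animals (896) the count was 403 from processed intensities, 358 with median centring, 4733 in the separate-channel fit, 353 with at least 2-fold change, and 57 to 2140 with 1 array left out. In Il6-deficient animals (803) it was 326, 358, 3016 and 356, with 2194 under array weights and 37 to 1187 with 1 array left out. For Il6 deficiency in controls it was 1 in the separate-channel fit and 0 to 3 with 1 array left out; in cryolesioned animals it was 1 and 0 to 0. For the mean of both states (1) it was 2 without background correction, 0 from processed intensities, 0 with scaled ratios, 0 with median centring, 0 without a dye intercept, 3 with array weights, 2 with a trended and robust variance, 2 over all probes, 0 with at least 2-fold change, 1584 with sex as a covariate, 2 with a dye intercept per slide end, and 0 to 168 with 1 array left out. The interaction gave 0 to 1 with 1 array left out.

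The replicate numbers of the labels paired the animals weakly if at all. Of 24 same-numbered pairs 10 correlated above 0.1 (range -0.25 to 0.53), and 7 of 16 animals correlated best with their own number. Among pairs on different arrays 8 of 20 same-numbered pairs exceeded 0.1 (median 0.067), against 19 of 68 differently numbered pairs (median -0.020). Whether the numbers pair the animals stays open. With the replicate block the log-ratio fit called 337, 6 and 0 genes for cryolesion in floxed, in Il6-deficient animals and for the mean of both states, with 2 residual degrees of freedom, and lost 102 of the 164 named calls. The separate-channel fit with the replicate block called 5140 and 3252 for cryolesion and 1 for Il6 deficiency in each state.

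The fitted ratio of the brighter Il6 probe for cryolesion in floxed animals was 0.56. This ratio is no fold because floxed controls were not well above background. It ranged from 0.36 to 0.70 with 1 array left out. Il6 passed neither the main 4-of-16 filter nor the 12-of-16 filter, so this ratio was fitted without a filter. Gene lists called by camera fell from 24, 23, 21, 23, 25 and 9 in the 6 contrasts to 0 in each with an estimated correlation, and fry called 15, 12, 0, 1, 3 and 0. The correlation of the cryolesion changes was 0.936 among genes passing in the separate-channel fit, which are selected for large changes (0.794 over all). Slide as a random block was not run. The fitted Il6 ratio was 2.62 from processed intensities, 1.07 with an offset of 16 and 1.30 in the authors' value table.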

Other observations

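The tests on Cx3cr1 were all chosen after the result was seen.

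Cx3cr1 was lower in Il6-deficient animals in both states, by -0.93 (95% interval -1.06 to -0.80). Fewer microglia in the tissue is argued against as the whole cause: the other 19 homeostatic microglia genes had a median of -0.0822 (bootstrap interval -0.17 to 0.06, range -0.44 to 0.39), and 0 of them lay below -0.80. The median was -0.20 in controls (bootstrap interval -0.26 to -0.09) and 0.01 in cryolesioned animals (-0.01 to 0.23). Cx3cr1 had 95% intervals of -1.23 to -0.77 and -1.09 to -0.62 there. The bootstrap intervals resample genes, so they reflect the spread among genes and not that between animals, and are unlike those of Cx3cr1. A smaller loss of microglia in controls stays open. In cryolesioned animals it stays open too, because the lists differed there. With sex as a covariate the median was -0.33 for activated phagocyte genes and -0.19 for complement genes, against -0.01 for the homeostatic microglia list with Cx3cr1. A sequence variant under a single probe is argued against as well, since the other Cx3cr1 probe gave -0.85. A candidate explanation is the loss of 1 of 2 Cx3cr1 copies, as in animals carrying a recombinase inserted in that gene, and the interval of the -0.93 change holds -1. That of the other probe, -0.98 to -0.72, does not hold it, so this explanation stays open. The labels do not name the recombinase line, and fewer transcripts per microglial cell through another route would give the same value.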
